A study of Rattus norvegicus with 24 samples.

How the data were processed

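RNA was sequenced from lung and liver of Sprague Dawley rat pups at postnatal day 6. Pups had received vehicle (2.5% ethanol), dexamethasone at 0.1 mg/kg or desisobutyryl ciclesonide at 1.25 mg/kg as 5 daily subcutaneous injections from postnatal day 1, and tissue was taken 24 hours after the last injection. There were 24 libraries in 6 groups of 4, grouped by the tissue, treatment and replicate number in the sample titles. Per the labels' protocols, total RNA was extracted with Trizol, polyadenylated RNA was selected and libraries were prepared with a directional dUTP kit. The submitters' processing notes name cutadapt, HISAT2, HTSeq and the rat build mRatBN7.2, without versions or settings, so whether the counting used strand is not given in the sources used here. Counts of overlapping, antisense and near-identical genes are uncertain for that reason.

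The deposited files hold whole-number counts per gene as the authors made them, not normalized, for 30560 Ensembl gene identifiers, followed by 5 summary rows for reads that were not assigned to a gene. The summary rows took 16.8% to 31.8% of each library's entries. They were kept out of library sizes and tests, and their shares were compared between groups with two-sided exact permutation tests, adjusted by the Benjamini-Hochberg method over 48 tests. With 4 libraries against 4 the smallest p these permutations can give is 0.0286.

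The files do not pair the identifiers with gene names. The table of 47357 rat genes at hand holds no Ensembl identifiers, and 0 of the 30560 identifiers matched it. Genes are therefore given by identifier, and the tests of 31 gene lists, the genes set to be reported in any case and the covariate built from Y-linked genes, all fixed before the data were examined, could not be run. The rule for naming genes, also fixed beforehand, took the largest rises and falls by log2 fold change among genes with an adjusted p under 0.05, a mean of at least 2 CPM in the higher group and log2 CPM values that did not overlap between the groups. It was applied without its condition on gene symbols and, for want of names, shortened to 2 genes each way per comparison. For the tissue difference non-overlap was not asked, and the mean had to reach 2 CPM in the higher group of each tissue.

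Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes passing the default expression filter were scaled by TMM, a quasi-likelihood model with robust dispersion was fitted to the 12 libraries of a tissue with 1 mean per treatment, and treatments were compared by the quasi-likelihood F-test with Benjamini-Hochberg adjustment at 0.05. All adjusted p-values for single genes come from this test unless another tool is named. The difference in response between tissues was tested in all 24 libraries as the lung change less the liver change, over genes that passed the filter in each tissue. Values per gene are CPM on the TMM-scaled library sizes. A fold against a group without any count is a lower bound against a floor of 3 counts over the 4 libraries of the group. Bounds and the 95% exact binomial interval given for a ratio resting on few counts cover counting error only.

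In place of the gene lists, 2 sets were formed after the data were seen from the 8 vehicle libraries. They hold the genes at least 16-fold higher in vehicle lung than in vehicle liver (1010 genes, called lung-enriched here) and the converse (738 genes, liver-enriched), out of 15294 tested. These sets were tested with camera from limma 3.58.1 at its preset correlation of 0.01 and with an estimated correlation, adjusted over 12 tests. The vehicle libraries that define them also enter the comparisons with vehicle, so sets defined from the treatment outside the comparison were an alternative. For the comparison between the drugs a definition from dexamethasone libraries was tried and dropped after its values had been seen, because dexamethasone is part of that comparison and vehicle is already the treatment outside it.

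Lung and liver libraries of the same treatment and number deviated together from their group means in all 12 pairs (Pearson r across 13245 genes from 0.114 to 0.316), and each lung library correlated best with the liver library of its own number. The numbers were therefore taken to mark pups across tissues. The labels do not say so, and a fit with the pup as a block was an alternative for the tissue difference. Because the labels do not name litters, p-values describe the spread between these libraries. No replicate pair agreed within sampling noise: chi-square per degree of freedom was at least 11.6 in the 36 pairs within groups, so all libraries were counted.

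Both drugs were compared with the same vehicle libraries. Unchanged groups drawn around the observed mean of those vehicle libraries were simulated 50 times per tissue. The error of that mean, which both drugs share, is thus left out of the simulated correlation and covariance. The simulated groups in place of dexamethasone had at most 1 called gene, so they give no overlap to compare. The observed overlap was computed again with the vehicle libraries parted into 2 and 2. The test was tried on simulated counts with 200 genes changed. Of those changed 2-fold, 68.0% were recovered for dexamethasone against vehicle in lung (15613 genes) and 56.0% in liver (13454 genes). Of those changed 4-fold, 86.0% and 92.0% were recovered, with 8 false calls among 143 in lung and 5 among 140 in liver. Only these 200 genes were changed, far fewer than were called in the data. The false calls therefore do not test scaling under changes of that extent. The recovered shares do not carry over to the data either, because the adjusted threshold is stricter when few genes change.

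The alternatives were RLE scaling, scaling from genes under 1% of counts, no expression filter, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, a replicate block, a minimum of 2-fold and leaving out each library in turn. Alternatives added after the data were seen left out lung dexamethasone replicates 3 and 4, and all alternatives for the tissue-enriched sets were added then.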

Results

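Gene expression was measured by RNA-seq in lung and liver of neonatal rats given vehicle, dexamethasone or desisobutyryl ciclesonide, with 4 libraries per tissue and treatment. Dexamethasone is a synthetic glucocorticoid, and desisobutyryl ciclesonide is the active metabolite of the glucocorticoid ciclesonide. The design asks how the drugs change gene expression in each tissue and how their effects differ. The doses differed, 0.1 mg/kg against 1.25 mg/kg, so no comparison between the drugs is at a matched dose. Libraries held 15839958 to 27881158 gene counts in lung and 15397992 to 26194384 in liver. Between 18390 and 19404 genes were detected in lung libraries and between 15958 and 17080 in liver libraries. The 10 most abundant genes took 7.04% ± 0.496 (SD, n = 4) of the counts in vehicle lung and 30.7% ± 0.768 in vehicle liver.

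Treatment separated the libraries in both tissues. The first principal component held 52.2% of the variance in lung and 59.9% in liver, and on it the 4 dexamethasone libraries lay apart from the other 8. Lung dexamethasone replicates 3 and 4 lay apart from replicates 1 and 2 on component 2, which held 16.1% of the variance. This was not particular to the pair (-34.9 and -48.1), as lung desisobutyryl ciclesonide replicate 4 lay further out on the same side (-53.5). Lung vehicle replicate 3 (-24.9) lay on that side too, apart from the other vehicle libraries.

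**Figure D1:**
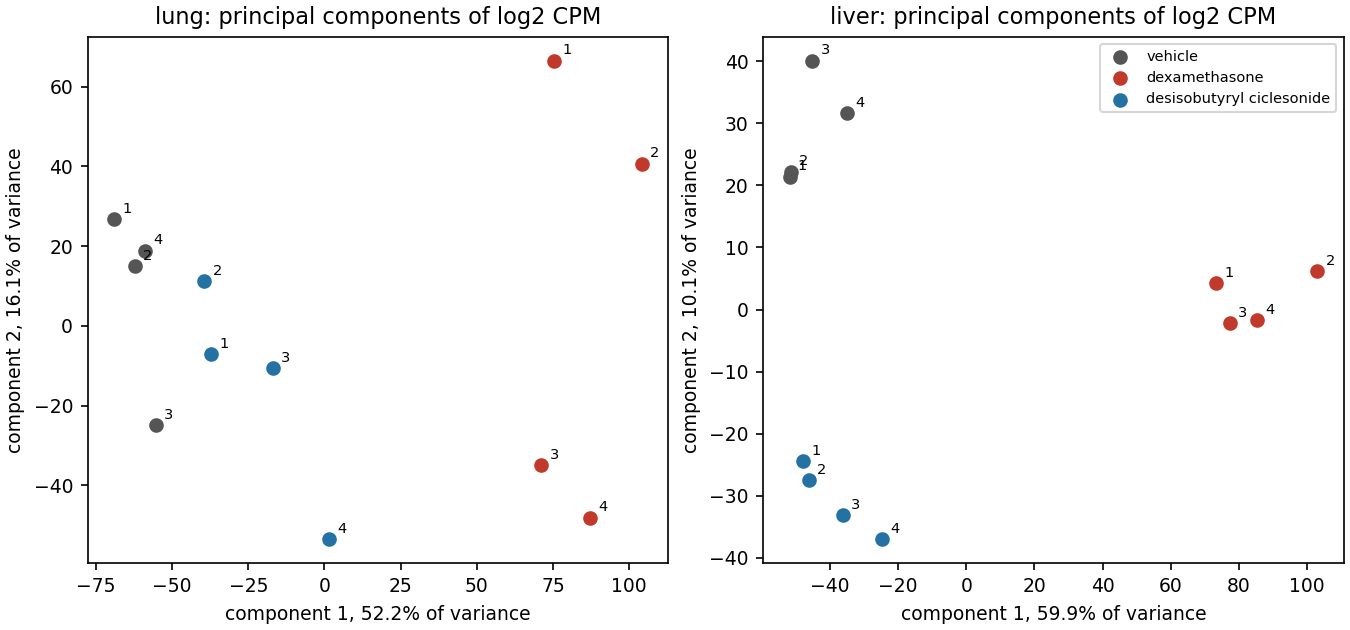
Principal components of log2 CPM in lung (left) and liver (right), with each point a library, coloured by treatment and numbered by replicate; the axes give the share of variance. Dexamethasone libraries lie to the right on component 1, which holds 52.2% of the variance in lung and 59.9% in liver.

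The desisobutyryl ciclesonide libraries also differed from the rest in their read categories. In lung, 1.08% ± 0.158 (SD, n = 4) of entries were unaligned, against 2.64% ± 0.287 with vehicle and 2.66% ± 0.706 with dexamethasone. In liver the shares were 1.10% ± 0.258, 2.69% ± 0.522 and 2.20% ± 0.227. Values did not overlap between desisobutyryl ciclesonide and vehicle in either tissue (exact permutation p = 0.0286, the smallest possible; adjusted p = 0.0549, which misses the threshold). The deposited file names also number these 8 libraries in a series apart from the other 16. Library series and drug thus coincide in every comparison that involves desisobutyryl ciclesonide, and no value within a series can be given.

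**Figure D2:**
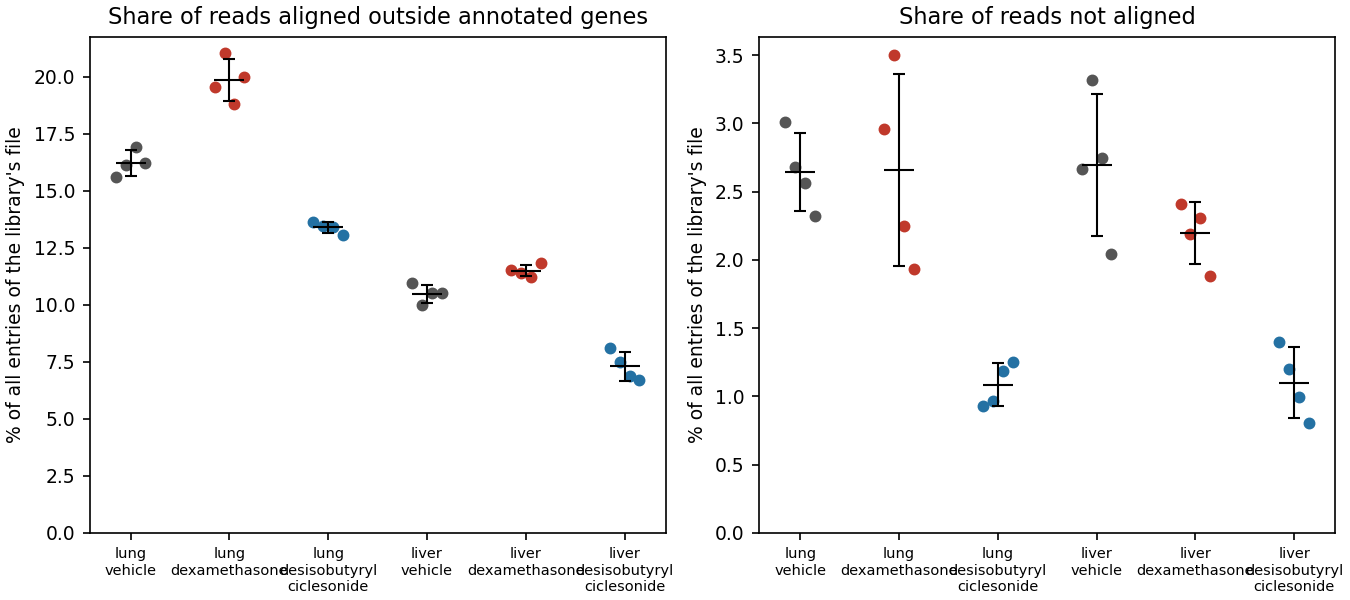
Share of each library's entries aligned outside annotated genes (left) and not aligned (right), in percent; points are libraries, and bars give the mean and SD of 4 libraries per group. The unaligned share averages 1.08% and 1.10% with desisobutyryl ciclesonide in lung and liver and at least 2.20% in the other groups.

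Dexamethasone changed 8961 of 16108 genes tested in lung, or 55.6%. Of these, 4337 rose and 4624 fell, and 1927 and 1957 did so by at least 2-fold. The genes that rose took 23.9% ± 0.571 (SD, n = 4) of the counts with vehicle and 43.0% ± 2.06 with dexamethasone, while those that fell went from 36.2% ± 0.437 to 18.98% ± 1.32. Groups did not overlap in 50.3% of genes tested, where chance gives 2.86%. Among the largest rises, ENSRNOG00000023151 reached 19.2 ± 4.46 CPM (adjusted p = 0.000103) and ENSRNOG00000069485 reached 7.60 ± 1.22 CPM (adjusted p = 1.01e-05). Neither had a count in the vehicle libraries, so they were at least 541-fold and 219.5-fold higher. Among the largest falls, ENSRNOG00000009662 at 5.71 ± 2.06 CPM and ENSRNOG00000020945 at 2.56 ± 0.529 CPM with vehicle had no count with dexamethasone, at least 174-fold and 77.8-fold lower (adjusted p = 0.00265 and 4.51e-05).

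Among liver-enriched genes, which were compared with lung and no other tissue, more rose than fell in lung under dexamethasone. Of 414 liver-enriched genes measured in lung, 172 rose, 42 fell and 200 did not pass the test, with a median log2 change of 0.75 (camera adjusted p = 1.17e-05; adjusted p = 0.0135 with an estimated correlation). The set holds 738 genes, and a gene can pass the expression filter in lung through the drug libraries in which it rose, so this count favours rises. Without the filter 182 of 713 rose and 47 fell (median 0.63, camera adjusted p = 0.000791; adjusted p = 0.155 with an estimated correlation). Of the 282 that pass it in vehicle libraries alone, a choice that favours falls, 117 rose and 42 fell (median 0.54, camera adjusted p = 0.000378; adjusted p = 0.0758 with an estimated correlation). Lung-enriched genes went both ways: 258 of 1010 rose and 348 fell, with a median log2 change of -0.04 (camera adjusted p = 0.436). Both sets were formed after the data were seen. In lung dexamethasone replicates 3 and 4, 20 genes, picked out after the data were seen, stood at least 4-fold above every other lung library and summed to 1553 and 4694 CPM, against at most 65.8 CPM elsewhere in lung. Without these 2 libraries 8497 genes were changed, and the medians were 0.52 for liver-enriched and -0.35 for lung-enriched genes. With the sets defined from desisobutyryl ciclesonide libraries the lung-enriched median was 0.35 (camera adjusted p = 0.170), so no direction is given for that set. The liver-enriched median was then 0.60 (camera adjusted p = 0.00134), and its call was lost with an estimated correlation (adjusted p = 0.0834).

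**Figure D3:**
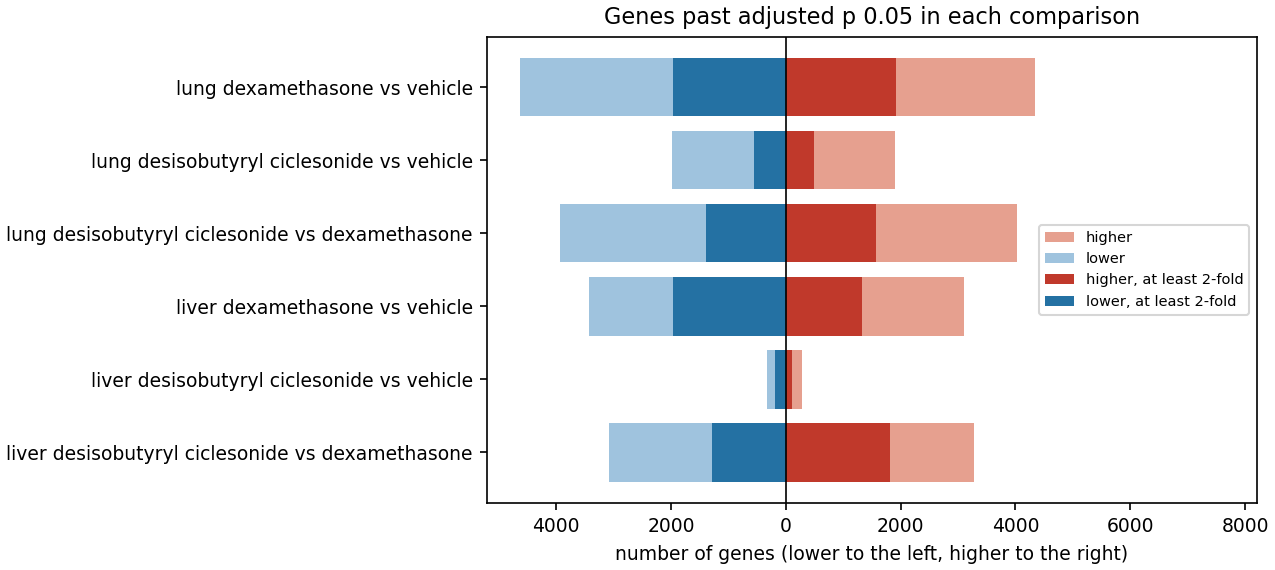
Number of genes past an adjusted p of 0.05 in the 6 comparisons within a tissue, lower to the left and higher to the right; dark bars count those changed by at least 2-fold. The longest bars are those of dexamethasone in lung (4337 higher, 4624 lower), and the shortest are those of desisobutyryl ciclesonide in liver (287 higher, 334 lower).

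Desisobutyryl ciclesonide changed 3884 genes in lung, or 24.1% of those tested, with 1895 higher and 1989 lower. Most changes were modest: 498 genes rose and 557 fell by at least 2-fold. The risers took 13.7% ± 0.674 (SD, n = 4) of the counts with vehicle, 21.7% ± 1.69 with desisobutyryl ciclesonide and 24.3% ± 0.977 with dexamethasone. ENSRNOG00000065108 rose from 0.346 ± 0.161 to 31.3 ± 24.2 CPM (log2 change 6.44, SE 0.80, adjusted p = 0.000458) and stood at 10.99 ± 7.64 CPM with dexamethasone. ENSRNOG00000032871 rose from 1.05 ± 0.680 to 29.5 ± 25.6 CPM (log2 change 4.76, SE 0.85, adjusted p = 0.00385) and stood at 95.3 ± 50.7 CPM with dexamethasone. ENSRNOG00000008478 fell from 189 counts to 2 over the 4 libraries of each group, a ratio of 82.4 (95% counting interval 22.5 to 686; adjusted p = 0.000165). ENSRNOG00000030738 fell from 2.21 ± 0.584 to 0.140 ± 0.104 CPM (log2 change -3.89, SE 0.54, adjusted p = 0.000426). Leaving out lung desisobutyryl ciclesonide replicate 3 lowered the count of changed genes to 2564.

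Among liver-enriched genes, more also rose than fell in lung under desisobutyryl ciclesonide. Of the 414 measured, 114 rose and 7 fell, with a median log2 change of 0.58 (camera adjusted p = 3.87e-09; adjusted p = 0.00397 with an estimated correlation). The expression filter favours rises here too. Without it 109 of 713 rose and 5 fell (median 0.69, camera adjusted p = 1.21e-07, and adjusted p = 0.0301 with an estimated correlation), and of the 282 that pass it in vehicle libraries alone 83 rose and 6 fell (median 0.45, camera adjusted p = 7.19e-09, and adjusted p = 0.0114 with an estimated correlation). Of 1010 lung-enriched genes, 234 rose and 70 fell, with a median of 0.29 (camera adjusted p = 0.000863). The call for the lung-enriched set was lost with an estimated correlation (adjusted p = 0.403). With sets defined from dexamethasone libraries, which the comparison does not use, the medians were 0.37 for liver-enriched (camera adjusted p = 0.000567) and 0.46 for lung-enriched genes (camera adjusted p = 3.07e-10). Both calls were then lost with an estimated correlation (adjusted p = 0.0834 for each).

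In lung the drugs shared many changed genes, and desisobutyryl ciclesonide moved them less. Both drugs raised 1373 genes and lowered 1237, and 182 genes were called in opposite directions. Independent lists of these sizes would share 510 and 571. Same-direction calls made up 67.2% of the genes called for desisobutyryl ciclesonide and 29.1% of those called for dexamethasone. Among the 2610 shared genes, the change was smaller with desisobutyryl ciclesonide in 1314, larger in 47 and not told apart in 1249 by the direct test, with a median ratio of log2 changes of 0.639. The log2 changes correlated across genes, which are not independent replicates, with Pearson r = 0.586 and covariance 0.515. Unchanged groups simulated 50 times around the observed mean of these vehicle libraries gave a mean r of 0.0744 and a mean covariance of 0.00588. This leaves out the error of the vehicle mean that both drugs share, so the simulations do not measure what shared controls add. With the vehicle libraries parted between the drugs, 943 to 1446 genes were shared, 25 to 125 were called in opposite directions and r lay between 0.448 and 0.515.

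**Figure D4:**
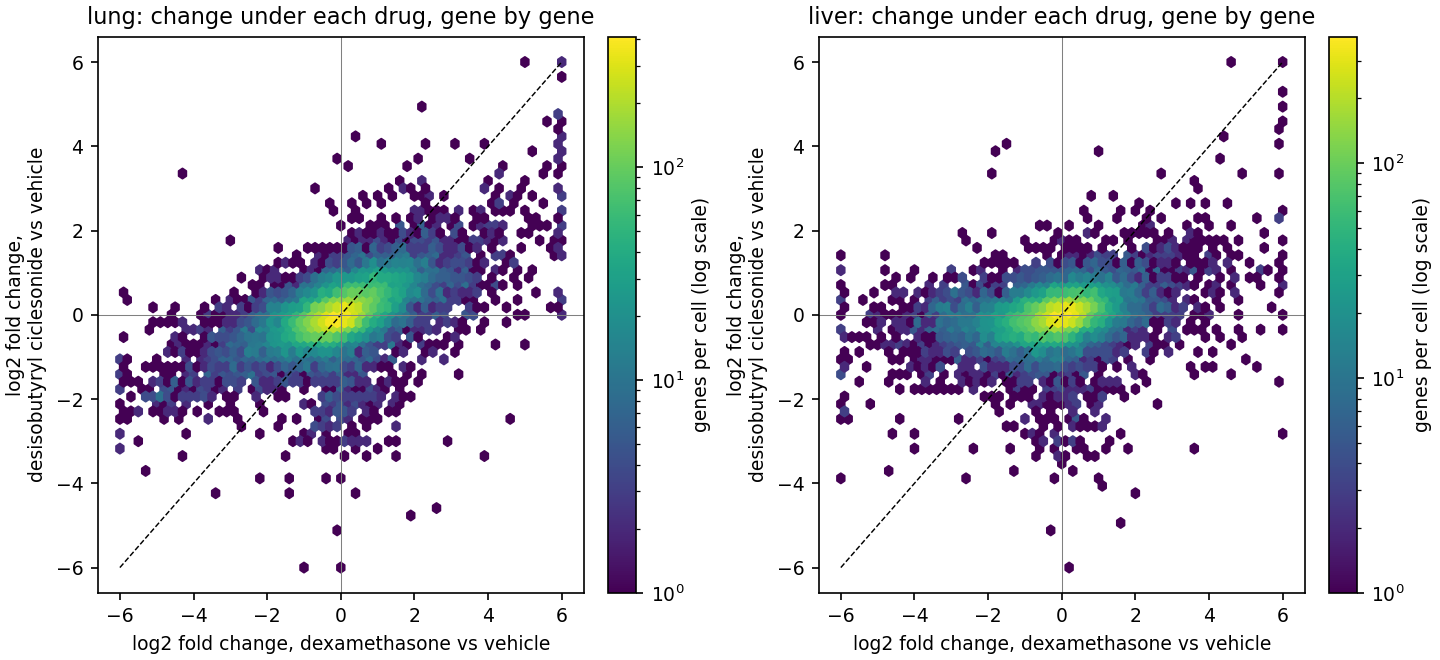
Log2 fold change against vehicle under dexamethasone (horizontal) and desisobutyryl ciclesonide (vertical) in lung (left) and liver (right), with genes binned in hexagons, colour giving their number on a log scale, and values beyond 6 drawn at the edge; the dashed line marks equal changes. Pearson r across genes is 0.586 in lung and 0.321 in liver.

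Tested directly in lung, 7966 genes differed between the drugs, 4028 higher and 3938 lower with desisobutyryl ciclesonide than with dexamethasone. Of the 6169 genes called for dexamethasone alone, 4700 differed in the direct test, with the larger change under dexamethasone. For genes without a called difference, the median 95% interval of the log2 difference was 0.40 either way, so smaller differences were not excluded. ENSRNOG00000009662 stood at 3.77 ± 4.02 CPM (SD, n = 4) with desisobutyryl ciclesonide and without a count with dexamethasone, at least 133-fold higher (adjusted p = 0.00487). ENSRNOG00000003776 was at 8.63 ± 3.56 against 0.0654 ± 0.0813 CPM (log2 difference 6.90, SE 0.66, adjusted p = 5.92e-06). ENSRNOG00000020276 and ENSRNOG00000015155 were lower with desisobutyryl ciclesonide by log2 differences of -8.56 (SE 2.11, adjusted p = 0.00795) and -7.61 (SE 1.95, adjusted p = 0.00969). They stood at 0.222 ± 0.127 and 0.625 ± 0.125 CPM with desisobutyryl ciclesonide and at 86.7 ± 123 and 122 ± 172 CPM with dexamethasone. Both belong to the 20 genes that were high in dexamethasone replicates 3 and 4. Without dexamethasone replicates 3 and 4 the log2 differences were -1.92 (adjusted p = 0.0933) and -0.44 (adjusted p = 0.444). With limma-voom the adjusted p was 0.292 and 0.314, and over all alternatives it ranged from 1.36e-07 to 0.292 and from 4.89e-08 to 0.444. Lung-enriched genes were higher with desisobutyryl ciclesonide in 360 of 1010 cases and lower in 118, with a median of 0.32 (camera adjusted p = 0.000863, lost with an estimated correlation, adjusted p = 0.403). Without dexamethasone replicates 3 and 4 that median was 0.62. Of 414 liver-enriched genes 62 were higher and 102 lower (median -0.05, camera adjusted p = 0.220).

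In liver, dexamethasone changed 6522 of 13734 genes tested, or 47.5%. Of these, 3096 rose and 3426 fell, and falls of at least 2-fold (1972 genes) outnumbered such rises (1331 genes). The genes that rose went from 26.6% ± 0.963 (SD, n = 4) to 50.5% ± 3.49 of the counts, and the genes that fell went from 26.9% ± 1.57 to 8.84% ± 1.34. ENSRNOG00000069485, also among the largest rises in lung, reached 5.18 ± 2.15 CPM, and ENSRNOG00000019124 reached 4.84 ± 6.20 CPM. Neither had a count in vehicle liver, so they were at least 125-fold and 108-fold higher (adjusted p = 3.00e-05 and 0.0104). ENSRNOG00000019660 at 5.54 ± 3.68 CPM and ENSRNOG00000067491 at 4.03 ± 0.522 CPM with vehicle had no count with dexamethasone, at least 126-fold and 91.8-fold lower (adjusted p = 0.000163 and 1.34e-06). Liver-enriched genes went both ways, with 180 of 738 higher and 280 lower and a median log2 change of -0.23 (camera adjusted p = 0.0942; adjusted p = 0.693 with an estimated correlation). Without liver dexamethasone replicate 3 the median was -0.25 and the set passed at the preset correlation (camera adjusted p = 0.0401). No value at an estimated correlation is given for that fit. The set also passed without the expression filter (median -0.24, camera adjusted p = 0.0372, lost with an estimated correlation, adjusted p = 0.668). Of 219 lung-enriched genes measured, 42 rose and 57 fell (camera adjusted p = 0.837). The 125 that pass the filter in vehicle libraries alone, a choice that favours falls, had a median of -0.65 (camera adjusted p = 0.0205, lost with an estimated correlation, adjusted p = 0.478).

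Desisobutyryl ciclesonide changed 621 genes in liver, or 4.52% of those tested, with 287 higher and 334 lower. The genes that fell went from 4.98% ± 0.457 (SD, n = 4) to 2.18% ± 0.687 of the counts and stood at 1.19% ± 0.0450 with dexamethasone. ENSRNOG00000014008 rose from 0.512 ± 0.377 to 46.5 ± 37.3 CPM (log2 change 6.49, SE 0.77) and ENSRNOG00000021513 from 0.124 ± 0.114 to 9.56 ± 3.54 CPM (log2 change 6.22, SE 0.51), with adjusted p of 0.00140 and 5.69e-06. With dexamethasone they stood at 96.6 ± 35.7 and 2.95 ± 0.884 CPM. ENSRNOG00000032085 fell from 2.91 ± 0.922 to 0.0876 ± 0.0896 CPM (log2 change -4.95, SE 0.67) and ENSRNOG00000055485 from 6.30 ± 2.05 to 0.397 ± 0.257 CPM (log2 change -3.96, SE 0.40), with adjusted p of 0.000996 and 5.84e-05. Dexamethasone raised both, ENSRNOG00000032085 to 9.19 ± 5.44 and ENSRNOG00000055485 to 13.7 ± 4.51 CPM (adjusted p = 0.00647 and 0.00746). Liver-enriched genes showed 36 rises and 32 falls among 738 (median 0.07, camera adjusted p = 0.289), and 2 of 219 lung-enriched genes rose and 1 fell (median 0.05, camera adjusted p = 1.00). With sets defined from dexamethasone libraries both passed, with medians of 0.16 (camera adjusted p = 0.00348) and -0.22 (camera adjusted p = 0.0449). Neither passed with an estimated correlation (adjusted p = 0.368 for each). The count of changed genes depended on the tool and the libraries: DESeq2 called 1151. It was 358, 295 and 374 without liver vehicle replicates 2, 3 and 4, and 409, 379 and 322 without liver desisobutyryl ciclesonide replicates 2, 3 and 4.

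The drugs shared 307 changed genes in liver, 169 higher and 138 lower, and 48 were called in opposite directions. Independent lists would share 64.7 and 83.3. Same-direction calls made up 49.4% of the genes called for desisobutyryl ciclesonide and 4.71% of those called for dexamethasone. The shared genes changed less with desisobutyryl ciclesonide in 112 cases, more in 10 and were not told apart in 185. The log2 changes correlated across genes with Pearson r = 0.321 and covariance 0.224. The simulations gave means of 0.0232 and 0.00127, which again do not measure what shared controls add. With the vehicle libraries parted, 50 to 135 genes were shared, 7 to 93 were called in opposite directions and r lay between 0.120 and 0.325. The split with 135 shared genes was the one with 93 opposite genes, with 5519 and 524 genes called for the drugs and r = 0.120. The number that independent lists would share was not computed for the splits of either tissue. The shared count was 153, 127 and 185 without liver vehicle replicates 2, 3 and 4, 184 and 146 without liver desisobutyryl ciclesonide replicates 3 and 4, and 567 with DESeq2.

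The direct test in liver called 6358 genes between the drugs, 3273 higher and 3085 lower with desisobutyryl ciclesonide. Of the 6167 genes called for dexamethasone alone, 4726 differed in this test, with the larger change under dexamethasone. ENSRNOG00000067491 at 4.13 ± 1.53 CPM (SD, n = 4) and ENSRNOG00000019660 at 2.96 ± 2.18 CPM had no count with dexamethasone, so they were at least 91.1-fold and 64.9-fold higher (adjusted p = 1.52e-06 and 0.000480). ENSRNOG00000011250 had no count with desisobutyryl ciclesonide against 7.88 ± 6.25 CPM with dexamethasone, at least 233-fold lower (adjusted p = 0.000140). ENSRNOG00000046643 was at 0.0563 ± 0.0652 against 52.6 ± 23.2 CPM (log2 difference -9.57, SE 0.53, adjusted p = 1.41e-07). Liver-enriched genes were higher with desisobutyryl ciclesonide in 280 of 738 cases and lower in 143, with a median of 0.28 (camera adjusted p = 0.0124, lost with an estimated correlation, adjusted p = 0.491, and without liver desisobutyryl ciclesonide replicate 4, adjusted p = 0.127). Of 219 lung-enriched genes 45 were higher and 41 lower (camera adjusted p = 0.869). The median 95% interval for genes without a called difference was 0.43 either way on the log2 scale.

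The response to dexamethasone differed between lung and liver for 4601 of the 13245 genes tested in both tissues. For both drugs this test took the 24 libraries as independent, though lung and liver libraries of a number were taken as 1 pup. Blocked by pup, the count for dexamethasone was 5046. Without the block, the change was more positive in lung for 2241 and more negative for 2360. Dexamethasone raised 1588 genes and lowered 1909 in both tissues, where independent lists would share 804 and 1002. It moved 636 genes in opposite directions, each past the test of the difference. Of the 3532 genes called in lung alone, 1653 differed between tissues by that test, and of the 2092 called in liver alone, 1340 did. ENSRNOG00000020647 went from no count to 2.37 ± 1.36 CPM (SD, n = 4) in lung, at least 66.6-fold higher, and stood at 14.8 ± 5.46 and 8.77 ± 2.58 CPM in vehicle and dexamethasone liver (adjusted p of the difference 1.21e-05). ENSRNOG00000008986 fell from 25.9 ± 2.59 to 2.09 ± 0.563 CPM in lung and rose from 5.95 ± 1.43 to 91.3 ± 32.6 CPM in liver, a log2 difference of -7.54 (SE 0.37, adjusted p = 3.51e-12). ENSRNOG00000028896 rose from 0.262 ± 0.439 to 32.4 ± 14.96 CPM in lung and fell from 1407 ± 329 to 413 ± 65.4 CPM in liver, a log2 difference of 8.77 (SE 0.81, adjusted p = 7.95e-08). ENSRNOG00000013598 fell from 26.3 ± 1.52 to 0.567 ± 0.132 CPM in lung and stood at 5.83 ± 1.93 and 16.7 ± 18.4 CPM in vehicle and dexamethasone liver, a log2 difference of -6.98 (SE 0.73, adjusted p = 3.61e-07).

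The response to desisobutyryl ciclesonide differed between the tissues for 571 genes, 306 more positive and 265 more negative in lung. With scaling from genes under 1% of counts the split was 409 and 225. The drug raised 100 genes and lowered 167 in both tissues, against 31.6 and 42.9 for independent lists, and moved 20 in opposite directions. Of the 3087 genes called in lung alone, 405 differed between tissues by the test of the difference, so most calls in a single tissue do not show a tissue difference. ENSRNOG00000032085 rose from 11.99 ± 2.69 to 22.8 ± 3.24 CPM in lung (SD, n = 4) while it fell in liver, from 2.91 ± 0.922 to 0.0876 ± 0.0896 CPM, a log2 difference of 5.92 (SE 0.67, adjusted p = 1.65e-05). ENSRNOG00000021513 stood at 2.24 ± 1.46 and 2.03 ± 0.0923 CPM in vehicle and treated lung while it rose in liver, a log2 difference of -6.40 (SE 0.72, adjusted p = 1.65e-05). ENSRNOG00000006198 fell from 11.7 ± 2.18 to 2.73 ± 1.01 CPM in lung and stood at 1.82 ± 0.758 and 4.04 ± 1.55 CPM in vehicle and treated liver (log2 difference -3.21, SE 0.60, adjusted p = 0.00269). ENSRNOG00000002889 stood at 1.02 ± 0.758 and 10.6 ± 18.04 CPM in vehicle and treated lung and fell from 28699 ± 4859 to 11400 ± 5177 CPM in liver, a log2 difference of 4.70 (SE 1.29, adjusted p = 0.0394). Its call was lost with lung and liver blocked by pup (log2 difference 3.08, adjusted p = 0.164) and without lung desisobutyryl ciclesonide replicate 2 (2.21, adjusted p = 0.201), and over all alternatives the adjusted p ranged from 0.00140 to 0.365. A fit of only the 4 groups compared called 944 genes and DESeq2 called 967.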

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

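The comparison of read categories, the tests of the library series and the counts over other splits of the libraries were chosen after the results were seen.

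The counts of changed genes were ranked against those of other splits of the libraries. A real split that ranks first of 35 is the strongest result these splits allow. Every other split mixes libraries of both treatments, which widens the fitted spread, so the size of its count adds no evidence. The splits do not test litters or the library series. For each of the 6 comparisons within a tissue, 1 of the 35 splits of the 8 libraries, the real one, gave as many genes. The real counts in lung were 8961, 3884 and 7966, and the highest other split gave 0, 0 and 1. In liver they were 6522, 621 and 6358, and the highest other split gave 1 in each. The response to dexamethasone differed between lung and liver for 4601 genes and that to desisobutyryl ciclesonide for 571, by the test of the difference itself. With the lung and liver libraries of a pup moved together, 1 of 35 splits gave as many genes for either drug, and the highest other splits gave 0 and 1.

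Several shares of reads outside the gene counts lay above vehicle without overlap. The share aligned outside annotated genes was 19.8% ± 0.931 (SD, n = 4) with dexamethasone against 16.2% ± 0.556 with vehicle in lung, and 11.5% ± 0.256 against 10.5% ± 0.399 in liver. The ambiguous share in liver was 3.28% ± 0.295 with dexamethasone against 2.77% ± 0.152. The share not uniquely aligned with desisobutyryl ciclesonide was 3.78% ± 0.558 against 2.90% ± 0.189 in lung and 3.68% ± 0.294 against 3.09% ± 0.0726 in liver. Other shares lay below vehicle without overlap. With desisobutyryl ciclesonide the share aligned outside annotated genes was 13.4% ± 0.241 in lung and 7.29% ± 0.639 in liver, and the unaligned share was 1.08% ± 0.158 and 1.10% ± 0.258. With dexamethasone the share not uniquely aligned in liver was 2.66% ± 0.179. Each has an exact permutation p of 0.0286, the smallest possible, and an adjusted p of 0.0549.

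The desisobutyryl ciclesonide libraries form a series of their own, so part of their difference from vehicle may come from library preparation or sequencing. With each drug set against its own 2 vehicle libraries, the lowest r across genes in lung was 0.448. This argues against the series as the whole cause there only if a series effect is unrelated to the dexamethasone changes, which was not tested. In liver the lowest r was 0.120, which does not decide. For genes that desisobutyryl ciclesonide changed against both other groups while dexamethasone did not (unadjusted p of 0.05 or more), 744 in lung and 225 in liver, drug and series cannot be told apart, because 0 libraries of another treatment belong to the series. Among genes tested in both tissues, 61 of these fell and 9 rose in both, against 3.91 and 1.58 for independent lists, and the lung and liver changes of the 636 lung genes correlated at r = 0.797, against 0.397 for 2290 lung genes shared with dexamethasone. Lung and liver libraries of the same number were taken as the same pup, so the tissues share pup deviations. Independent lists, here and in the other overlaps of lung with liver, do not allow for that. No r for unchanged groups was computed.

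Of 90 groups of 4 values tested, 3 held a library far from the others, where chance gives about 1 in 20. This is no more than chance gives, so these libraries are listed but not taken as outliers. Liver desisobutyryl ciclesonide replicate 4 had 26194384 gene counts against 17111433 to 17379969 in the other 3, a gap of 0.970 of the group's range. Liver vehicle replicate 2 had an ambiguous share of 3.00% against 2.67% to 2.72%, a gap of 0.841. ENSRNOG00000069485 stood at 5.78 CPM in lung dexamethasone replicate 3 against 7.99 to 8.34 CPM, a gap of 0.885 on the log2 scale.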

How the results depend on the processing

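Counts of genes stayed within 1.5 times the reported count under 71 settings and moved further under 13; with 1 library left out, 92 stayed and 12 moved. All settings of the tissue-enriched sets, and leaving out lung dexamethasone replicates 3 and 4, were chosen after the data were seen. Requiring at least 2-fold lowered the counts, by construction. In lung they became 3884 for dexamethasone, 1055 for desisobutyryl ciclesonide, 2958 between the drugs and 673 shared by both drugs. In liver they became 3303, 309, 3108 and 131. The tissue difference for dexamethasone became 2504. DESeq2 gave 1151 genes for desisobutyryl ciclesonide in liver, 567 shared in liver and 967 for the tissue difference of desisobutyryl ciclesonide, and a fit of only the groups compared gave 944 for the last; the cause was not tested.

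Leaving out 1 library, desisobutyryl ciclesonide changed 2564 to 3366 genes in lung and 295 to 482 in liver, and 127 to 405 genes were shared by both drugs in liver. Fewer libraries were fitted in each case. Without lung dexamethasone replicates 3 and 4, 8497, 4196 and 7604 genes were called in lung for dexamethasone, desisobutyryl ciclesonide and between the drugs.

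Across treatments the replicate numbers did not pair the libraries (r between -0.259 and 0.362 in lung and between -0.0929 and 0.107 in liver; 5 and 2 of 12 pairs matched best by number). The replicate block moved no count by over 1.5 times: it gave 442 genes for desisobutyryl ciclesonide in liver and 211 shared there. With lung and liver libraries blocked by pup, the tissue difference held 5046 genes for dexamethasone and 779 for desisobutyryl ciclesonide, and the call of ENSRNOG00000002889 was lost with either block (adjusted p = 0.0891 and 0.164). No other call of a named gene or set changed under a block.

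Named genes kept direction and call in 241 cases under other settings and in 309 with 1 library left out, and direction only in 10 and 11. The lost calls were those of ENSRNOG00000020276, ENSRNOG00000015155 and ENSRNOG00000002889. Sets kept their side of the threshold in 81 and 94 cases, lost it in 6 and 1 and passed it in 4 and 1. Without the expression filter liver-enriched genes in lung had medians of 0.63 (dexamethasone) and 0.69 (desisobutyryl ciclesonide), and with only members that pass it in vehicle libraries 0.54 and 0.45. Each call was kept at the preset correlation, and at an estimated correlation both were lost for dexamethasone (adjusted p = 0.155 and 0.0758). The counts of cases above leave out these fits at an estimated correlation. All 1010 lung-enriched genes pass it in vehicle lung, so that choice changes nothing for them there. With sets defined from the treatment outside the comparison, liver-enriched genes in lung had medians of 0.60 (dexamethasone) and 0.37 (desisobutyryl ciclesonide), and these calls were lost with an estimated correlation (adjusted p = 0.0834 for each). No scaling moved the median of all genes by over 0.1, but each assumes that most genes are unchanged. These medians therefore cannot show a shift shared by most genes. The gene lists and the Y-linked covariate were not run, for want of gene names. Of simulated genes changed 1.5-fold, 18.0% were recovered for dexamethasone in lung. Only 200 genes were changed there, so the adjusted threshold asked for a smaller unadjusted p than in the data. That rate therefore does not give the share of small changes missed in the data. For genes not called for dexamethasone in lung, the median 95% interval of the log2 change was 0.42 either way. Smaller changes were thus not excluded. Depth, spread and number of libraries were not varied apart.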

Other observations

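The counts over all 4 comparisons, Fisher's exact tests, the ratio between lung replicates and the match of lung with liver libraries were chosen after the results were seen, and the test of the share of liver RNA was added after the first test of liver RNA had been read, with its bounds set before its own values. Its form by summed counts was added after the medians had been read, and the counts of opposite genes with other sets and filters were also added later.

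Some genes were called in the same direction for both drugs in both tissues. Of 13245 genes tested in both tissues, 58 rose and 33 fell in all 4 comparisons with vehicle. The median log2 changes of the risers were 1.33 with dexamethasone and 0.80 with desisobutyryl ciclesonide in lung, and 1.46 and 1.01 in liver. Those of the genes that fell were -0.99 and -0.82 in lung and -0.92 and -0.83 in liver. The vehicle libraries of a tissue are shared between its comparisons, so this count is not one of independent overlaps. No number expected by chance was computed, and for desisobutyryl ciclesonide drug and library series coincide.

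Genes that rose in lung and fell in liver under dexamethasone included more liver-enriched genes than that set's share of all genes tested. The sets here come from desisobutyryl ciclesonide libraries, since vehicle libraries are the baseline of both changes and would favour such genes: of 337 genes that rose in lung and fell in liver, 36 were liver-enriched, against 9.19 by chance. Genes can also pass the expression filter through the dexamethasone libraries in which they rose, but of the 290 such genes that pass it in vehicle libraries alone, a choice that favours falls in lung, 19 were liver-enriched, against 5.60 by chance (two-sided Fisher's exact test across genes, p = 3.47e-06), and without the filter 34 of 312 were, against 10.4 (Fisher's exact p = 1.27e-09). Of 299 that fell in lung and rose in liver, 8 were lung-enriched, against 6.73 by chance (Fisher's exact p = 0.553). Genes are not independent replicates, so these p-values overstate the evidence, and the sets were formed after the data were seen.

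The rises among liver-enriched genes in lung under both drugs may come, among other sources, from liver RNA carried into the lung libraries or from a change in lung cells. Carried RNA would raise the genes most abundant in liver at least as much as the whole set. The median log2 change of the 20 most abundant was above that of the set by 0.306 with dexamethasone, less than 2 standard errors (0.870). With desisobutyryl ciclesonide it was above by 1.07. Of the 20, 6 rose and 2 fell with dexamethasone, and 9 rose and 0 fell with desisobutyryl ciclesonide. Liver RNA thus stays open for the rises among those 20 with either drug, though carried RNA alone would not lower the 2 that fell. The other genes called higher, 166 and 105, would need a share of liver RNA with medians of 9.68% and 5.58%. This is 350.2 and 79.4 times the median share of the 20 most abundant (0.0277%, quartiles 0.00121% and 0.300%, and 0.0703%, quartiles 0.0645% and 0.190%). The called genes were picked by their rise in lung and the 20 were not, which favours a high needed share. The gap argues against carried RNA as their whole cause only so far as that choice does not make it, which was not tested. Against the share from the summed counts of the 20 (0.546% and 0.211%) the needed share was 17.7 and 26.5 times as high, and over single libraries 7.38 to 63.0 and 11.5 to 42.8 times, so a response of lung cells remains a hypothesis for these genes, and with desisobutyryl ciclesonide the library series stays open as well.

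The 20 genes high in lung dexamethasone replicates 3 and 4 may reflect RNA of another tissue or a response in only these pups, and no value here decides between them. They stood in replicate 4 above replicate 3 by a median factor of 2.94, with an SD of 0.300 on the log2 scale, but the SD was also low (0.401) over 11021 other genes in the same range of levels, so this spread does not bear on a single source. Among the 17 other pairs of libraries within a lung group the most such genes was 2. This pair was picked after the data were seen, so its rank among the pairs does not test chance sharing. All 20 genes were among those called for dexamethasone against vehicle in lung. The same genes summed to at most 18.2 CPM in any liver library, so liver is no candidate source. Without gene names no tissue can be named.

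Within a treatment, each lung library correlated best across genes with the liver library of its own number in 12 of 12 cases, with a lowest r of 0.114, and the highest r with another number was 0.174.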
